A study of Homo sapiens with 6 samples.

How the data were processed

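RNA-seq libraries were made from hTERT RPE-1, a human retinal pigment epithelial cell line immortalised with telomerase. Per the labels' protocols, poly-A RNA was sequenced as paired 150-base reads on a NovaSeq instrument. The 6 libraries fell into 2 groups of 3, untreated cells and cells given a pre-dose of camptothecin, an inhibitor of topoisomerase 1. The pre-dose was 25 nM for 1 h, followed by 24 h without drug, per the labels. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

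The authors deposited a single table with 13773 rows. It held 13696 distinct gene identifiers, and the 77 rows that repeated an identifier were dropped. The deposited expression values were on a log2 scale in CPM, counts scaled to the library total. In each column the lowest value recurred, and when it was read as an estimated count of 0 with 0.5 added, the other low values fell on a grid of hundredths of a read. In every library 100% of the values under 200 reads lay on that grid, within 0.05 of a hundredth, and 53.0 to 55.8% of them were whole. These were therefore estimated counts deposited on a log2 scale by the authors, and not whole reads. The submitters' processing notes name bcl2fastq, DRAGEN, edgeR and limma and the build hg38, without versions or roles. The counting step, its strand setting, the annotation and the filter on genes are not given in the sources used here.

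The authors also deposited the result of their own comparison in the table, with log2 fold changes and confidence limits, a moderated statistic (a score), p-values and adjusted p-values, per the file headers. The sign of the deposited log2 fold change was untreated minus pre-dose, by comparison with the sample columns, and it was turned here to pre-dose minus untreated. The authors' model and any library weights are not given in the sources used here.

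The effective library totals implied by the lowest values were 26336941 to 31780391 reads. At these totals, 3 counts corresponded to 0.0944 to 0.114 CPM, a limit that covers counting error only.

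A test of whole counts was planned before the data were examined, for the case that counts had been deposited. As the values were normalized, the test fixed for that case was used: limma-trend on log2(CPM + 1), with a pseudocount of 1 CPM, on genes with a mean of at least 1 CPM over the 6 libraries. This left 13616 genes. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. R 4.3.3 and limma 3.58.1 were used, and figures were drawn with matplotlib 3.10.9.

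Before the data were examined, 26 gene lists were fixed. The 23 lists with at least 5 measured genes were tested with camera, a competitive two-sided test of limma, with a preset inter-gene correlation of 0.01. Lists of keratinocyte and other epithelial, blood cell and neuronal markers had too few measured members (2, 3 and 3). For each list the members past the threshold over all genes tested, and adjusted over the list alone, were counted. Further lists, of actin and adhesion, ribosome biogenesis and fatty acid genes, were written after the values had been examined in part.

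The rule for named genes was fixed beforehand. It took genes past the threshold whose groups did not overlap, and CUL3, NEDD8, TOP1, TDP1, KEAP1, CDKN1A and MDM2 whatever their result. As fewer than 5 genes passed, it gave the 8 genes with the smallest unadjusted p in each direction, as not passing. Genes without an approved-style symbol, pseudogenes and sex-specific genes were left out of that part. Other members of a list were given as examples by their rank of p within it, and members behind a count of 5 or fewer calls were named after their values were seen.

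The groups share replicate numbers. Whether the numbers pair the libraries was checked from the deviations of each library from its group mean over the genes tested. The correlations across genes of same-numbered libraries were 0.66, 0.45 and 0.18 for replicates 1, 2 and 3. The numbers were taken to pair the libraries. Pairs of other numbers reached 0.51 (untreated replicate 3 and pre-dose replicate 2) and 0.28 (untreated replicate 2 and pre-dose replicate 3). Both were above the 0.18 of replicate 3. The strongest feature was that replicate 1 stood apart from both others. The labels do not state the pairing, and for replicates 2 and 3 these values do not settle it, so it is an assumption there. A fit with the replicate number as a block was an alternative.

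Gene positions, lengths and GC content came from GENCODE release 29 on GRCh38, in which 13630 of the identifiers were found, 97.4% of them with the same symbol. The submitters' annotation may differ from it.

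The fits were tested on simulated data with the real gene means and replicate offsets, 13616 genes and the residual spread of the blocked fit. Of 100 genes changed by 0.5 on the log2 scale, the fit without a block recovered 28, and of 100 changed by 1 it recovered 84, with 0 false calls. The blocked fit recovered 94 and 100, with 15 false calls. A fit of replicates 2 and 3 alone recovered 77 and 95, with 10 false calls. The simulated noise was independent between genes and each change was the same in every replicate. The recovered counts therefore do not carry over to changes that differ between replicates.

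Alternatives covered the scaling, the filter on low values, the pseudocount, voom on the recovered estimated counts, the replicate block, the omission of each library, library weights, removal of a GC trend, and list tests with an estimated correlation or with fry.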

Results

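Expression of 13616 genes was compared between 3 libraries of untreated hTERT RPE-1 cells and 3 libraries of cells harvested 24 h after a 1 h pre-dose of 25 nM camptothecin. hTERT RPE-1 is a telomerase-immortalised line of human retinal pigment epithelial cells. Camptothecin traps topoisomerase 1 on DNA. The series title concerns NEDDylated cullin 3 and the adaptive response to topoisomerase 1 inhibitors, and these libraries address what a low pre-dose does to gene expression. The effective library totals were 26336941 to 31780391 reads, and values are in CPM, counts scaled to the library total.

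The 2 replicate 1 libraries stood apart from the other 4. The first principal component held 59.4% of the variance and placed untreated replicate 1 at -20.6 and pre-dose replicate 1 at -18.0, with the other 4 libraries between 6.94 and 16.4. On the second component, with 15.2% of the variance, both pre-dose libraries of replicates 2 and 3 lay above their untreated partners, and the replicate 1 libraries lay at 2.75 and 0.25. With the treatment in the model, 5560 genes differed between replicate 1 and the other replicates in limma at an adjusted p of 0.05, 2761 higher and 2799 lower in replicate 1. The labels name no batch. Values are therefore also given within the replicate 1 pair, where 1 library per group allows no test, and within replicates 2 and 3.

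**Figure D1:**
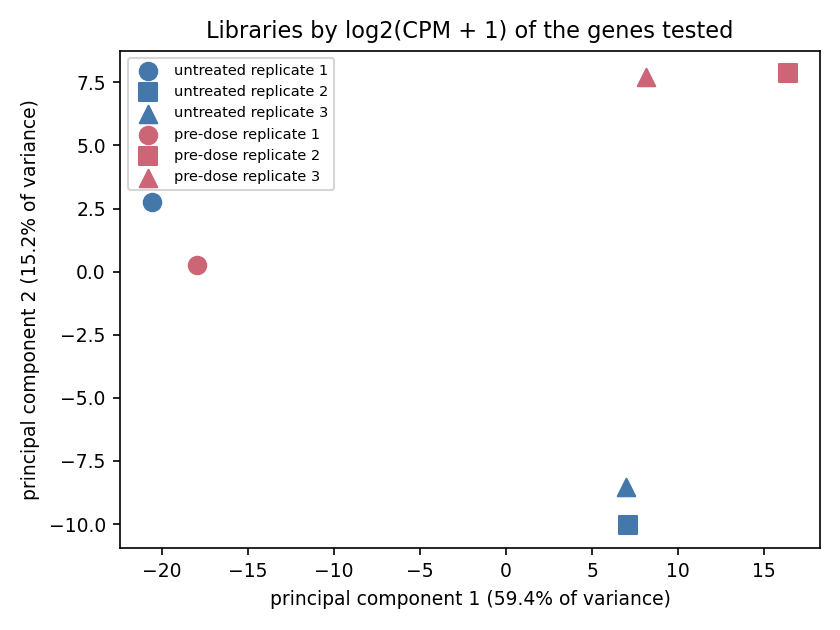
Positions of the 6 libraries on the first (x axis, 59.4% of variance) and second (y axis, 15.2% of variance) principal components of log2(CPM + 1), colored by group and with a marker shape per replicate number. The replicate 1 libraries lie at -20.6 and -18.0 on the first, and the other 4 between 6.94 and 16.4.

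Targets of the transcription factor p53 rose as a list in camera after the pre-dose, and did not pass with an estimated correlation (adjusted p = 0.522). The list's mean log2(CPM + 1) was 4.59 ± 0.10 (SD, n = 3) in untreated and 4.96 ± 0.28 (SD, n = 3) in pre-dose libraries. Of 42 measured targets, 35 were higher in all 3 pairs and 0 were lower in all 3. The median difference was 0.16, 0.43 and 0.33 on the log2 scale in the replicate 1, 2 and 3 pairs. Averaged over both groups, the list also stood lower in the replicate 1 libraries than in the others, by a median of -0.26. That value includes the smaller difference of the replicate 1 pair. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, had 208 ± 39.9 CPM (SD, n = 3) in untreated and 421 ± 184 CPM (SD, n = 3) in pre-dose libraries. Its level in pre-dose replicate 1, 217 CPM, was below those of untreated replicates 2 and 3, 229 and 233 CPM. MDM2, the ubiquitin ligase that targets p53, had 54.3 ± 4.11 CPM (SD, n = 3) in untreated and 78.9 ± 19.6 CPM (SD, n = 3) in pre-dose libraries. CYFIP2 went from 13.2 ± 2.93 to 27.3 ± 5.73 CPM (SD, n = 3 each) and FDXR, a mitochondrial ferredoxin reductase, from 14.4 ± 0.698 to 26.1 ± 7.02 CPM (SD, n = 3 each).

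The p53 list passed in camera with an adjusted p of 5.36e-31, and with a p of 0.0428 (adjusted p = 0.522) when the inter-gene correlation was estimated. An exact permutation test of the list mean gave a two-sided p of 0.1. It ignored the replicate numbers, and 3 libraries against 3 allow no smaller p. In limma, 0 of the 42 targets passed over all genes tested and 2, CYFIP2 and PHLDA3, passed when adjusted over the list alone, and with the replicate block 32 passed when adjusted over the list alone. The authors' deposited table had 24 of the 42 past an adjusted p of 0.05, all higher. In replicates 2 and 3 alone, a fit chosen after the data were seen, 30 were, all higher.

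**Figure D2:**
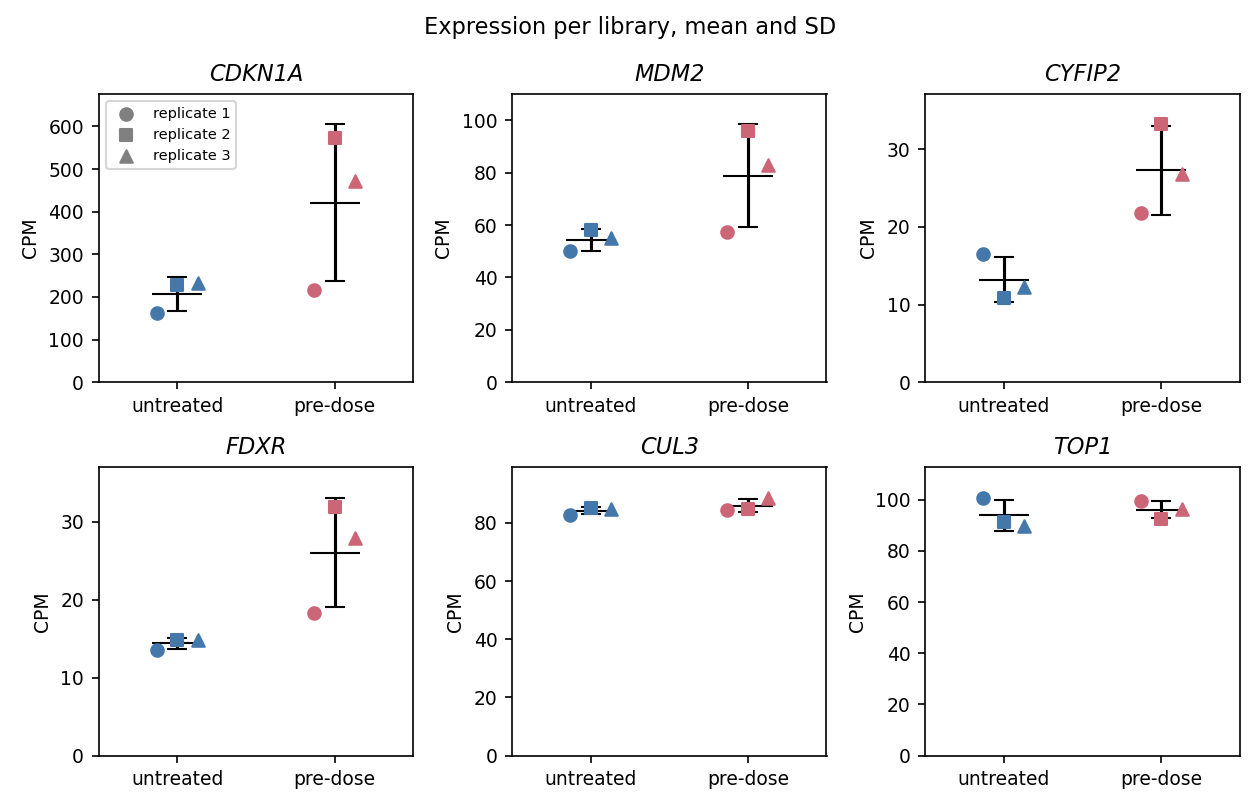
CPM (y axis, from 0) of CDKN1A, MDM2, CYFIP2, FDXR, CUL3 and TOP1 in untreated and pre-dose libraries (x axis). Points are libraries, with a marker shape per replicate number, and bars are the mean with the SD of 3 libraries. CDKN1A was 217 CPM in pre-dose replicate 1 and 573 and 472 CPM in pre-dose replicates 2 and 3.

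Genes of G2 and mitosis fell as a list in camera, and did not pass with an estimated correlation (adjusted p = 0.611). Their direction was not shared by the 3 pairs. The median difference was 0.21 in the replicate 1 pair, with 39 of 40 members higher, and -0.50 and -0.32 in the replicate 2 and 3 pairs, with 0 of 40 higher. The list mean was 6.50 ± 0.016 (SD, n = 3) in untreated and 6.30 ± 0.37 (SD, n = 3) in pre-dose libraries. Averaged over both groups, the list stood higher in the replicate 1 libraries than in the others, by a median of 0.37. The untreated list means had an SD of only 0.016, so this difference lay in the pre-dose libraries. BUB1B, a spindle checkpoint kinase, had 80.7 ± 7.87 CPM (SD, n = 3) in untreated and 66.8 ± 11.7 CPM (SD, n = 3) in pre-dose libraries. Its difference was 0.16, -0.52 and -0.47 on the log2 scale in the 3 pairs. MYBL2, a cell cycle transcription factor, differed by -0.25, -0.47 and -0.26. The list passed with an adjusted p of 9.60e-11 in camera, and its p was 0.233 (adjusted p = 0.611) with an estimated correlation. In limma 0 members passed, over all genes or adjusted over the list alone, and 1 did adjusted over the list alone with the replicate block. The authors' deposited table had 15 members past the threshold, all lower, and replicates 2 and 3 alone had 39, all lower.

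E2F targets and DNA replication genes fell in camera with an adjusted p of 0.00169 over 44 members, and homologous recombination and Fanconi genes with 3.43e-05 over 32 members. Their p values with an estimated correlation were 0.533 and 0.242 (adjusted p = 0.721 and 0.611). The E2F list had median differences of -0.05, -0.27 and -0.03 in the 3 pairs, and the recombination list 0.01, -0.25 and -0.06. Both stood higher in the replicate 1 libraries, by medians of 0.39 and 0.19. The direction of the E2F list turned without untreated replicate 1 (adjusted p = 0.546) or without pre-dose replicate 2 (adjusted p = 0.198). The recombination list lost its call without pre-dose replicate 2 (adjusted p = 0.484). In replicates 2 and 3 alone, the E2F and recombination lists passed as lower in camera (adjusted p = 7.17e-06 and 3.69e-06). CDC6, a replication licensing factor, had 43.9 ± 7.44 CPM (SD, n = 3) in untreated and 38.2 ± 6.91 CPM (SD, n = 3) in pre-dose libraries. FANCB had 4.04 ± 0.139 and 3.28 ± 0.0115 CPM (SD, n = 3 each), and BLM, a DNA helicase, 10.8 ± 0.468 and 9.41 ± 0.884 CPM (SD, n = 3 each). The authors' deposited table had 0 E2F list members past the threshold and 2 recombination list members, UBE2T and BRIP1, both lower.

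Cholesterol synthesis genes fell in camera with an adjusted p of 2.77e-06 over 23 members, 19 of which were lower in all 3 pairs. Their median differences were -0.10, -0.20 and -0.32, and the p with an estimated correlation was 0.227 (adjusted p = 0.611). The list stood lower in the replicate 1 libraries by a median of -0.51. EBP, a sterol isomerase, had 50.04 ± 0.501 CPM (SD, n = 3) in untreated and 45.0 ± 2.13 CPM (SD, n = 3) in pre-dose libraries, and MVK, the mevalonate kinase, 33.7 ± 5.46 and 27.8 ± 2.66 CPM (SD, n = 3 each). The authors' deposited table had 3 members past the threshold, MVK and NSDHL among them, all lower. In limma 0 members passed, over all genes or adjusted over the list alone. With the replicate block, 18 members passed when adjusted over the list alone, 17 of them lower. The list's call was lost without pre-dose replicate 1 (adjusted p = 0.248), a fit in which the offset of untreated replicate 1 entered the contrast. In replicates 2 and 3 alone the list passed as lower in camera (adjusted p = 4.42e-16).

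NF-kB, hypoxia, ATF4 and matrix lists fell in camera as well. NF-kB and secreted inflammatory genes had an adjusted p of 1.31e-04, hypoxia and glycolysis genes 7.00e-04, ATF4 and unfolded protein response genes 0.0293 and TGF-beta and matrix genes 0.0375. With an estimated correlation the p values were 0.165, 0.125, 0.0454 and 0.610, and none passed after adjustment (adjusted p = 0.611, 0.611, 0.522 and 0.776). In the replicate 1 libraries the NF-kB, hypoxia and matrix lists stood lower, by medians of -0.35, -0.18 and -0.38. NFKBIA, the NF-kB inhibitor, had 26.9 ± 1.91 CPM (SD, n = 3) in untreated and 22.4 ± 1.62 CPM (SD, n = 3) in pre-dose libraries. XBP1 went from 54.6 ± 0.895 to 47.6 ± 1.68 CPM and ATF4 from 193 ± 3.76 to 173 ± 11.5 CPM (SD, n = 3 each), both transcription factors of stress responses. TAGLN, an actin-binding protein, had 1043 ± 120 and 863 ± 22.0 CPM (SD, n = 3 each). In limma 0 members of these lists passed, over all genes or adjusted over the list alone. With the replicate block, adjusted over the list alone, 4 NF-kB members passed (3 lower), 1 hypoxia member (lower), 6 ATF4 members (5 lower) and 7 matrix members (6 lower). The authors' deposited table had NFKBIA, NFKB2, IL32, XBP1, ATF4, MANF, PFKFB3, TAGLN and ITGA5 past the threshold as lower, and IL1B and SESN2 as higher. Without pre-dose replicate 1 the NF-kB (adjusted p = 0.299), hypoxia (0.222), ATF4 (0.160) and matrix (0.322, with its direction turned) lists lost their calls. Without untreated replicate 3 the hypoxia (0.0717) and matrix (0.826, turned) lists did, and the matrix list also did without untreated replicate 2 (0.512). The ATF4 list also lost its call without untreated replicate 1 (0.189) or pre-dose replicate 3 (0.119). These fits had no block, so with 1 replicate 1 library left out the offset of the other entered the contrast. In replicates 2 and 3 alone, the NF-kB, hypoxia, ATF4 and matrix lists passed as lower in camera (adjusted p = 3.17e-04, 6.31e-07, 0.0334 and 0.00193).

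Mitochondrially encoded transcripts rose in camera with an adjusted p of 0.00169 over 13 members and median differences of 0.03, 0.12 and 0.06 in the 3 pairs. With an estimated correlation its p was 0.348 (adjusted p = 0.635). The list stood lower in the replicate 1 libraries by a median of -0.19. The call was also lost without untreated replicate 1 (adjusted p = 0.546), pre-dose replicate 2 (0.170) or pre-dose replicate 3 (0.0892). Cytosolic ribosomal protein genes did not pass (adjusted p = 0.0629 in camera), and passed as higher with the replicate block (adjusted p = 0.00855, and 0.594 with the block and an estimated correlation), without untreated replicate 1 (7.37e-04) or without pre-dose replicate 2 (0.00239). In the list tests as a whole, 10 of 23 lists passed in camera, 2 higher and 8 lower, and 0 passed with an estimated correlation or with fry. The estimated correlations of those 10 ran from -0.017 (ATF4) to 0.89 (mitochondrial), against the preset 0.01. Exact permutation of their list means gave a p of 0.1 for the p53 and ATF4 lists and 0.4 for G2 and mitosis. It gave 0.5 for the others that passed. The permutation ignored the replicate numbers, so offsets of the replicate 1 libraries counted as spread in it. In replicates 2 and 3 alone, 12 lists passed in camera, among them each of those 10 in the same direction.

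**Figure D3:**
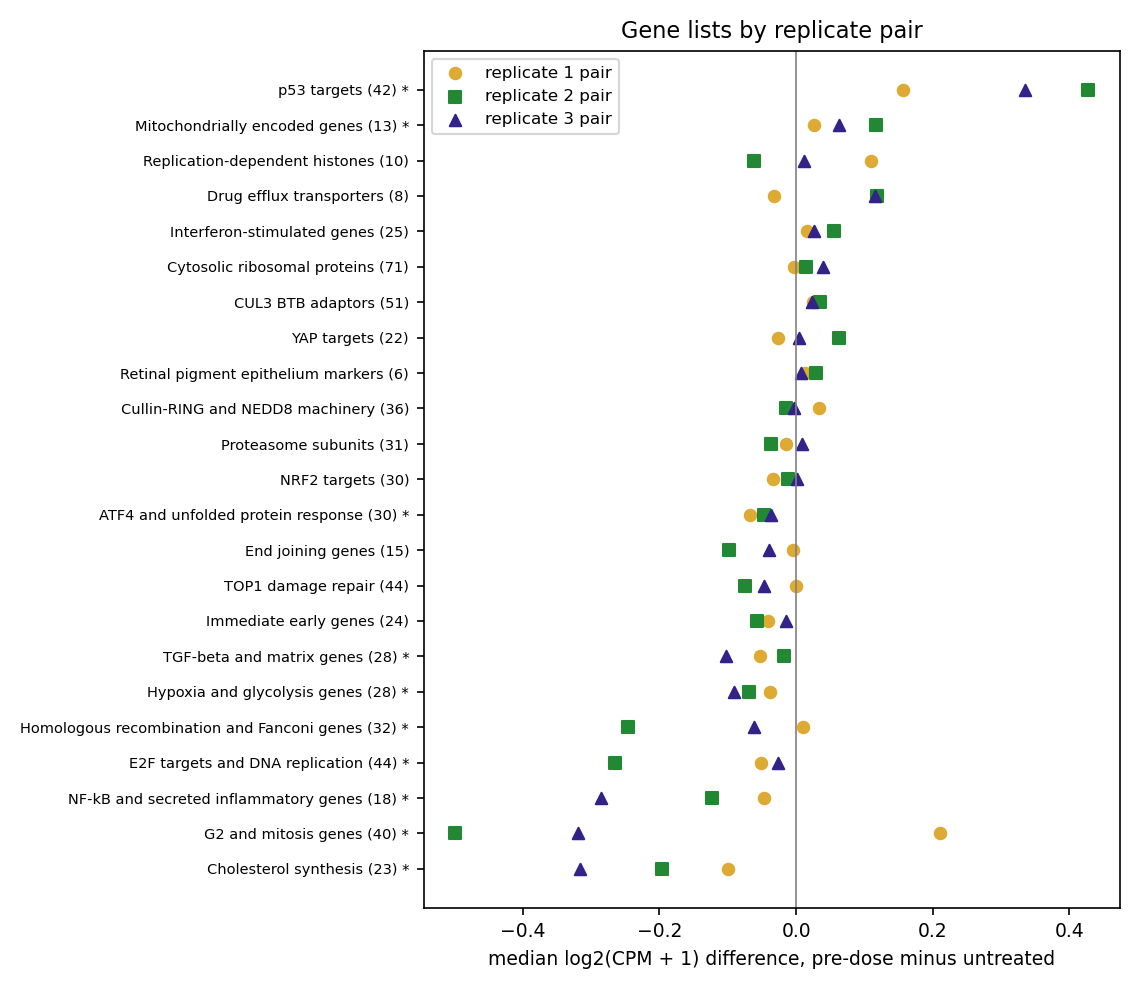
Median difference in log2(CPM + 1), pre-dose minus untreated (x axis), of the measured members of each of the 23 lists tested (y axis, number of members in parentheses), with a marker per replicate pair. An asterisk marks lists past an adjusted p of 0.05 in camera with the preset correlation. The p53 targets lie at 0.16, 0.43 and 0.33, and the G2 and mitosis genes at 0.21, -0.50 and -0.32.

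Lists that bear on the title of the series did not pass. The Cullin-RING and NEDD8 machinery had an adjusted p of 0.727 in camera over 36 members, with median differences of 0.033, -0.015 and -0.0030 in the 3 pairs. The adaptors that join substrates to cullin 3 had 0.190 over 51 members, and TOP1 damage repair genes 0.183 over 44. KLHL3, a cullin 3 adaptor, had 7.72 ± 0.436 CPM (SD, n = 3) in untreated and 10.1 ± 1.01 CPM (SD, n = 3) in pre-dose libraries, and was past the threshold in the authors' deposited table (adjusted p = 0.0331). CUL9 was the member of the cullin list past it there (adjusted p = 0.0467). Without pre-dose replicate 1 the TOP1 repair list passed as lower (adjusted p = 0.0407), and the interferon-stimulated list passed as higher without it (0.0101) or without untreated replicate 3 (0.0212). NRF2 targets (0.546), interferon-stimulated genes (0.164), YAP targets (0.482), end joining genes (0.267), proteasome subunits (0.468), drug efflux transporters (0.151), replication-dependent histones (0.546), retinal pigment epithelium markers (0.629) and immediate early genes (0.998) did not pass in camera, values being adjusted p. In replicates 2 and 3 alone the efflux list passed as higher (adjusted p = 0.0360). The proteasome list passed as lower without untreated replicate 2 (0.0311), untreated replicate 3 (0.0275) or pre-dose replicate 1 (9.67e-04), and as higher without untreated replicate 1 (0.0211). It stood higher in the replicate 1 libraries by a median of 0.17, an offset that enters the contrast when 1 library is left out without a block. In the immediate early and cullin lists the median was below 0 and the mean above it.

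CUL3, on chromosome 2 from 224470150 to 224585397 (GRCh38), had 84.2 ± 1.28 CPM (SD, n = 3) in untreated and 86.0 ± 2.28 CPM (SD, n = 3) in pre-dose libraries. The log2 difference was 0.03, with a 95% interval of -0.10 to 0.15. NEDD8, the ubiquitin-like modifier, lies on chromosome 14 from 24216852 to 24232454 and had a difference of -0.01 with an interval of -0.15 to 0.13. TOP1, the target of camptothecin, lies on chromosome 20 from 41028818 to 41124487 and differed by 0.03, with an interval of -0.12 to 0.19. TDP1, which removes trapped topoisomerase 1, differed by -0.04 (-0.27 to 0.19), and KEAP1, a cullin 3 adaptor for NRF2, by 0.10 (-0.21 to 0.41). None of these genes passed in limma, the smallest unadjusted p being 0.482, and the authors' deposited table gave them adjusted p values from 0.116 to 0.629. CDKN1A (chromosome 6, 36676460 to 36687339) differed by 0.92 with an interval of 0.11 to 1.73, and MDM2 (chromosome 12, 68808176 to 68850686) by 0.50 with an interval of 0.09 to 0.91. Neither passed after adjustment in limma, and the authors' deposited table gave both an adjusted p of 0.0254.

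Across all 13616 genes, limma-trend called 0 genes at an adjusted p of 0.05 and 280 at an unadjusted p under 0.05, 170 of them higher. Voom on recovered estimated counts called 0 as well, and 278 at an unadjusted p. The replicate block called 0 and raised the unadjusted count to 1443, with a smallest adjusted p of 0.138. The replicate 1 pair allows no test. Replicates 2 and 3 alone gave 866 genes, 394 higher and 472 lower. Voom with library quality weights, which gave both replicate 1 libraries the lowest weights, called 108 genes, 66 higher and 42 lower. Both of these were chosen after the data were seen. Groups did not overlap for 892 genes, 6.55% of those tested, where chance gives 10% for exchangeable libraries. Libraries paired by replicate number are not exchangeable, so the shares are not a test.

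The authors' deposited table held 418 genes past an adjusted p of 0.05, 220 higher and 198 lower after the pre-dose. Of the 415 among the genes tested here, 351 were also called in the same direction in replicates 2 and 3, and 0 in the opposite one. Those 4 libraries are among the 6 of this series, so the calls are not independent of that table. The replicate 1 pair differed in sign from both others for 158 of the 415 genes of the authors' deposited table. The fold changes of that table had a Pearson correlation across genes of 0.62 with those of limma-trend and 0.986 with those of voom with library quality weights, all from the same libraries, and genes are not independent replicates.

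The genes with the smallest unadjusted p did not pass after adjustment, their adjusted p being 1.00 in limma. HSPA4L, a heat shock protein family member on chromosome 4 (127781821 to 127840733), had 15.7 ± 0.635 CPM (SD, n = 3) in untreated and 21.1 ± 0.901 CPM (SD, n = 3) in pre-dose libraries, with a log2 difference of 0.40 ± 0.07 (SE). CYFIP2 differed by 0.99 ± 0.19 (SE), OSBPL3 by 0.32 ± 0.07, PHLDA3 by 0.32 ± 0.07, FDXR by 0.78 ± 0.19, GTF2IRD2 by 0.44 ± 0.11, GDNF by 0.52 ± 0.13 and KRT15 by 0.32 ± 0.08. CYFIP2, PHLDA3 and FDXR belong to the p53 list, and GDNF encodes a neurotrophic factor. GTF2IRD2 has near-identical copies on chromosome 7, so its value is uncertain. On the lower side, CSRP1, an actin-associated LIM protein on chromosome 1 (201483530 to 201509456), had 322 ± 10.3 and 272 ± 17.2 CPM (SD, n = 3 each), a difference of -0.25 ± 0.06 (SE). CRISPLD2 differed by -0.34 ± 0.09 (SE), ARHGAP33 by -0.25 ± 0.07, XBP1 by -0.20 ± 0.06, SPOCD1 by -0.20 ± 0.06, HIC1 by -0.22 ± 0.07, XYLT1 by -0.20 ± 0.06 and DHRS7B by -0.25 ± 0.08. Each of the genes named here kept its direction in all 3 pairs, which follows largely from picking them by p in these same libraries. In the authors' deposited table, from the same libraries, all but HIC1 (adjusted p = 0.0716) and DHRS7B (adjusted p = 0.0564) were past the threshold.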

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

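The scalings (total scaling was planned for lists), the deposited log2 scale, the batch term, the restriction to replicates 2 and 3, both kinds of library weights, the GC correction, and for lists the filter and the pseudocount were chosen after the data were seen. The planned count-model tests, edgeR and DESeq2, were not run, since the values are not whole counts. The count of 0 genes stayed 0 with each scaling, filter, pseudocount and left-out library, and by voom, the block, the batch term, the deposited log2 scale and the GC correction. It became 866 in replicates 2 and 3, 108 by voom with library quality weights and 3744 by limma-trend with library weights, which rested on pre-dose replicate 3 with a weight of 28.8. With replicate 1 as a batch term in limma-trend, the smallest adjusted p was 0.0547, close to the threshold. In that fit 1684 genes had an unadjusted p under 0.05. Named genes kept their direction and side of the threshold in 382 comparisons with another setting, passed it in 51 and turned in 4. Single lists kept both in 338, lost their call in 32, gained one in 15 and turned in 29. With a library left out and no block, the offset of replicate 1 enters the contrast. Each list that passed in camera also passed in the same direction with the replicate block, and in replicates 2 and 3 alone. The share of the offset in the changes above was not tested further.

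With the replicate block, 0 genes and 11 lists passed, and of the list calls only that of the ribosomal proteins changed. With the block and an estimated correlation 0 lists passed. The count of lists was 0 with an estimated correlation and 0 by fry, which tests no contrast with other genes. Adjusted p values were then 0.522 and 0.606 for the p53 list, and 0.611 and 0.794 for both the G2 and mitosis and the cholesterol lists. The immediate early list turned, without passing, with no filter (0.998), the replicate block (0.230), total scaling (0.924), upper-quartile scaling (0.873), the batch term (0.437), replicates 2 and 3 (0.830) and the GC correction with the block (0.373). In replicates 2 and 3 the Cullin-RING (0.811), histone (0.830) and retinal pigment epithelium (0.830) lists turned as well.

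With each library left out in turn, the log2 difference of NEDD8 ran from -0.046 to 0.017 and that of TDP1 from -0.13 to 0.019. The adjusted p ran from 4.23e-11 to 0.546 for the E2F list, 0.451 to 0.977 for Cullin-RING, 0.0407 to 0.986 for TOP1 repair, 0.281 to 0.986 for NRF2 and 0.0101 to 0.878 for interferon-stimulated genes. It ran from 0.271 to 0.876 for immediate early genes, 1.96e-09 to 0.826 for matrix, 0.178 to 0.892 for YAP, 0.146 to 0.811 for histones, 9.67e-04 to 0.632 for the proteasome, 0.433 to 0.986 for retinal pigment epithelium markers and 8.64e-16 to 0.248 for cholesterol synthesis. At these totals 3 counts stood for up to 0.114 CPM, so depth limits only the lowest genes.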

Other observations

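The actin and fatty acid lists, and the tests of a label swap, of mixed RNA, of actin genes and of long genes, were chosen after related values had been seen. The tests with the GC trend removed were chosen after the values without its removal had been seen. Actin cytoskeleton and focal adhesion genes were lower after the pre-dose, with median differences of -0.03, -0.12 and -0.19 in the 3 pairs and 32 of 49 members lower in all 3. TPM4, a tropomyosin, had 1468 ± 5.51 CPM (SD, n = 3) in untreated and 1312 ± 67.5 CPM (SD, n = 3) in pre-dose libraries, and VASP, an actin regulator, 188 ± 7.17 and 163 ± 14.2 CPM (SD, n = 3 each). In camera the list's p was 1.10e-15, and 0.0275 with an estimated correlation. The authors' deposited table had 21 of the 49 past the threshold, all lower, and in limma 0 passed over all genes tested, with or without the replicate block. As the list was written after some of these genes had been seen, a lower level of actin and adhesion genes is a hypothesis that these libraries cannot test independently.

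Fatty acid synthesis genes had median differences of -0.04, -0.16 and -0.20 over 13 measured members. The list also stood lower in the replicate 1 libraries, by a median of -0.27 (camera p 2.85e-05, and 0.134 with an estimated correlation). FASN, the fatty acid synthase, had 801 ± 67.3 CPM (SD, n = 3) in untreated and 693 ± 42.4 CPM (SD, n = 3) in pre-dose libraries. The list's p in camera was 3.76e-04, and 0.217 with an estimated correlation. FASN and FADS1 were past the threshold, lower, in the authors' deposited table.

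The replicate 1 libraries stood apart, with MALAT1 lower (log2 difference -1.68) and the amino acid transporter SLC7A5 higher (0.78) in them. Among the genes with a known GC content, 5553 differed between replicate 1 and the others, and 5257 did with the GC trend of each library removed. The ratio of these counts was 0.947, and 4509 of the 5553 genes were among the 5257, which argues against a GC trend as the whole cause. Faster growth of these cultures is a candidate explanation. A list of ribosome biogenesis genes was higher in replicate 1 by a median of 0.35, with an unadjusted camera p of 0.0336 with an estimated correlation. E2F targets and G2 and mitosis genes had 0.153 and 0.387 (adjusted p = 0.440 and 0.643). Matrix genes, lower in replicate 1, had 0.0378 and proteasome subunits, higher, had 0.0481 (adjusted p = 0.379 for both). Such a p is therefore not particular to growth genes. The G2 and mitosis list mean had an SD of only 0.016 among the untreated libraries, so untreated replicate 1 did not stand apart in it. The ribosome biogenesis genes had not been examined before, but E2F targets and growth-linked genes such as SLC7A5 had been seen to be higher, and other differences between the cultures or preparations stay open.

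The p53 target difference was smaller in the replicate 1 pair. A swap of the labels in that pair would give a median below 0, and it was 0.16 (95% bootstrap interval over members 0.08 to 0.21). The swap was judged on this list alone, and other lists were divided. G2 and mitosis genes went as a swap would have it, with 39 of 40 higher in that pair and 0 of 40 in the others. Cholesterol synthesis genes did not, with 19 of 23 lower in that pair. With the GC trend removed, the p53 median of that pair stayed below the lower of the other pairs by -0.20 (interval -0.28 to -0.12). A mixture of treated and untreated RNA would lower the G2 and mitosis genes as in the other pairs, and their median was 0.17 (0.14 to 0.22). These intervals cover the members and not the noise between libraries, and with 1 library per group a weaker response in that pair was not tested.

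G2 and mitosis genes were higher in the replicate 1 pair alone. Before any removal, the pair's differences followed GC content with a Spearman rho across genes of -0.36, genes not being independent replicates. With the GC trend removed, the list's median was 0.17 (0.14 to 0.22), which argues against that trend as the whole cause. The interval covers the members and not the noise between libraries, with 1 library per group. A difference in growth between these cultures at harvest was not tested.

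The 6 libraries make 10 splits, too few for a share under 0.05. All 10 gave as many genes as the real split, with 0 in the real split and 0 as the highest other. No split can give fewer than 0 genes, so this comparison could decide nothing. As many lists came from 2 of the 10, the real value being 10 and the highest other 10, from the split that sets both replicate 1 libraries and pre-dose replicate 3 against the rest. Unadjusted counts reached 2973 where untreated replicates 1 and 3 were set with pre-dose replicate 1, against 280 in the real split, which points to a structure of the samples, and the blocked count of lists was 11. It was also 11 when the replicate 1 libraries were exchanged, with a blocked camera p of the G2 and mitosis list of 3.11e-52 against 6.58e-13 in the real split, and of the p53 list of 1.61e-12 against 4.82e-37. Among the splits that part all 3 pairs, the blocked unadjusted counts were 1443 in the real split, 1547 when the replicate 1 libraries were exchanged, and 155 and 134 in the others.

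Inhibition of topoisomerase 1 during treatment is known to slow transcription of long genes, so lower levels of long genes were tested. The cells were harvested after 24 h without drug, so only a difference that lasted until then could be seen. Genes of at least 100 kb (2374 genes) differed from shorter ones (9456 genes) by 0.02, 0.03 and 0.01 in the 3 pairs, a mean of 0.020 on the log2 scale, so they were not lower. The camera p was 0.0612, and 0.584 with an estimated correlation. With a limit of 50 kb the mean was 0.016 and with 200 kb 0.027.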
